A study of Homo sapiens with 6 samples.

How the data were processed

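RNA from 6 samples of H1-derived astrocytes was profiled with 3' end libraries of polyadenylated RNA, 3 control (forebrain) and 3 ventral midbrain. Per the submitters' processing notes, the authors used Salmon, with no version given, DESeq2 1.27.12 and the build GRCh38.p13. The deposited files hold, for each library, Salmon's estimated counts per transcript, TPM per transcript and effective transcript lengths for 226608 transcripts. The authors also deposited a table of normalized gene signal for 21509 genes. For 97.8% of 10644 comparable genes that signal equals, within 0.01 on the natural log scale, gene counts divided by factors that vary with library and gene length, and for 0.301% it equals counts divided by library factors. A 3' end read does not depend on transcript length, so no length factor entered the main test. TPM values, deposited by the authors, were not used for tests.

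Estimated counts were summed per gene with the GENCODE annotation in the box (GRCh38), matching 205225 transcripts (90.6%) by identifier without its version. Unmatched transcripts held 0.992% to 1.12% of the reads of a library. For 121 genes (1.14%) the deposited level lay more than 1.1 times off the sum used here, NFIA among them. Sums were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr, which left 15984 of 27439 genes with reads, and scaled by TMM. edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 tested ventral midbrain against control with Benjamini-Hochberg adjustment, the common biological coefficient of variation being 0.309. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use the TMM-scaled library size. Salmon divides reads between overlapping transcripts, so genes that overlap others, their antisense partners and paralogs are uncertain. Whether the counting used strand is not given in the sources used here.

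The 29 gene lists (640 genes, 496 tested) were fixed before the data were examined and tested with camera of limma 3.58.1 at a preset correlation of 0.01. None of the 9 calls held with an estimated correlation. With fry, which asks whether the genes of a list move, on balance, one way, the ventral midbrain and forebrain lists passed. Median and mean differ in sign in the neural crest (-0.09 and 0.08), Hedgehog (-0.05 and 0.05) and WNT (0.12 and -0.03) lists. Camera's direction is opposite to the median and mean in the oligodendrocyte lineage list.

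Named genes follow a rule fixed beforehand. They are the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with no overlap between groups and an average log2 CPM of at least 2. They also include, from each list, up to 6 members with the smallest p and up to 2 with the highest level, any member of the ventral midbrain, forebrain, hindbrain, astrocyte, neuron and Hedgehog lists, and the 5 genes with the smallest p. Values of a few genes that the rule names are not reported here, while the counts and list tests include them. The groups share the replicate numbers 2, 3 and 4. Deviations from the group means correlated between same-numbered samples at 0.234, 0.345 and 0.204, against at most 0.0237 for other pairs across groups. Same-numbered samples thus deviated together in these data. Deviations cancel out within each group of 3, so these correlations depend on each other and do not establish a pairing. No label says what the numbers share.

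The method was tested on simulated data for this comparison with 15434 genes tested. The changed genes were drawn from those with a mean CPM of at least 2 on the log2 scale, and no shared replicate effect was simulated. It recovered 33% of 100 genes changed 2-fold and 89% of 100 changed 4-fold, and 13 of 135 calls (9.63%) were false. Alternatives were RLE and upper-quartile scaling, no filter, a filter of 2 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a gene-length offset, the deposited normalized values on log2(value + 1), a replicate block, protein-coding genes alone, stricter thresholds and leaving out each library. Figures were drawn with matplotlib 3.10.9.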

Results

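Astrocytes derived from the H1 line, an established human embryonic stem cell line, were compared between 2 regional characters. The labels' source field and the series title name astrocytes, while their cell type field names the stem cells, and the samples are called astrocytes here. The labels call the groups control (forebrain) and ventral midbrain, with 3 libraries each, numbered 2, 3 and 4. RNA was measured with 3' end libraries, which read the end of each polyadenylated transcript. The libraries held 11617935 to 15391082 estimated reads, with 14574520, 11617935 and 14211353 in control and 15391082, 12477947 and 13506682 in ventral midbrain replicates 2, 3 and 4. Mitochondrially encoded genes took 11.1% ± 0.862 (SD, n = 3) of the reads in control and 10.9% ± 1.54 (SD, n = 3) in ventral midbrain libraries (two-sided exact permutation test, p = 0.8). Genes with at least 5 reads numbered 17560 ± 52.5 (SD, n = 3) and 17868 ± 215 (SD, n = 3), and that exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow. Correlations of log2 CPM were 0.940 to 0.956 within groups and 0.902 to 0.943 between groups. The first principal component held 35.7% of the variance, with the control libraries at -66.2 to -8.31 and the ventral midbrain libraries at 21.7 to 62.6.

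The comparison asks how astrocytes given a ventral midbrain character differ from the forebrain control. Of 15984 genes tested, 344 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 169 higher and 175 lower in ventral midbrain libraries. The change was at least 2-fold for 283 of them, and 323 were protein coding. In all 344 the libraries of the 2 groups did not overlap, which held for 17.9% of the tested genes. By chance it would hold for 10% if all libraries were independent, although same-numbered samples deviated together. A test of 3 against 3 libraries favours genes without overlap, so their presence in all 344 is no separate support for the calls. With the replicate number as a block, 1300 genes passed (581 higher and 719 lower), and 338 of the 344 were among them. The block leaves fewer degrees of freedom to estimate the spread from 6 libraries, and a pairing is not established. Blocked values given below therefore do not replace the calls of the main test. The count of 344 fell to 173 with a gene-length offset and to 131 without control replicate 4. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these samples.

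Of the ventral midbrain and floor plate genes, 3 rose past the test in ventral midbrain libraries. EN1, a homeobox gene of the midbrain and anterior hindbrain (chromosome 2, 118842171 to 118847678, GRCh38), went from 5.12 ± 1.35 CPM (SD, n = 3) to 202 ± 14.9 CPM (SD, n = 3), a log2 fold change of 5.31 ± 0.22 (SE; edgeR adjusted p = 2.3e-06). EN2, its paralog, rose from 2.02 ± 0.50 to 29 ± 15.5 CPM (edgeR adjusted p = 0.0062). NKX6-1, a ventral neural tube homeobox gene, rose from 0.495 ± 0.121 to 6.46 ± 3.84 CPM (edgeR adjusted p = 0.011). These 3 of the 14 measured members of the ventral midbrain and floor plate list rose and 11 did not pass, while 6 higher and 1 lower passed when adjusted over the list alone. LMX1B was at 0.322 and 2.57 CPM and WNT1 at 0.407 and 2.43 CPM in control and ventral midbrain libraries (edgeR adjusted p = 0.13 and 0.16). PAX8 was at 126 and 295 CPM (edgeR adjusted p = 0.25, and 0.00038 with the replicate block). OTX2, a forebrain and midbrain gene, was at 17.6 and 2.33 CPM (edgeR adjusted p = 0.24, and 0.0014 with the replicate block). SHH was at 14.0 and 11.8 CPM, LMX1A at 0.607 and 0.658 CPM, and FOXA2 at 0.110 and 0.418 CPM, too low to be tested. No read was assigned to CORIN, FERD3L, SIM1 or BARHL1 in any library, so these were not detectable at this depth. As a list the genes stood higher than other genes (camera adjusted p = 0.028), with adjusted p = 0.47 with an estimated correlation. Of the 14 fold changes 9 were positive and 5 negative, with a median of 0.20 against a mean of 1.17 on the log2 scale. The EN2 call was lost without control replicate 2 or 4 (highest adjusted p = 0.062), and the NKX6-1 call without control replicate 4 or ventral midbrain replicate 4 (highest adjusted p = 0.066), and voom called neither.

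**Figure D1:**
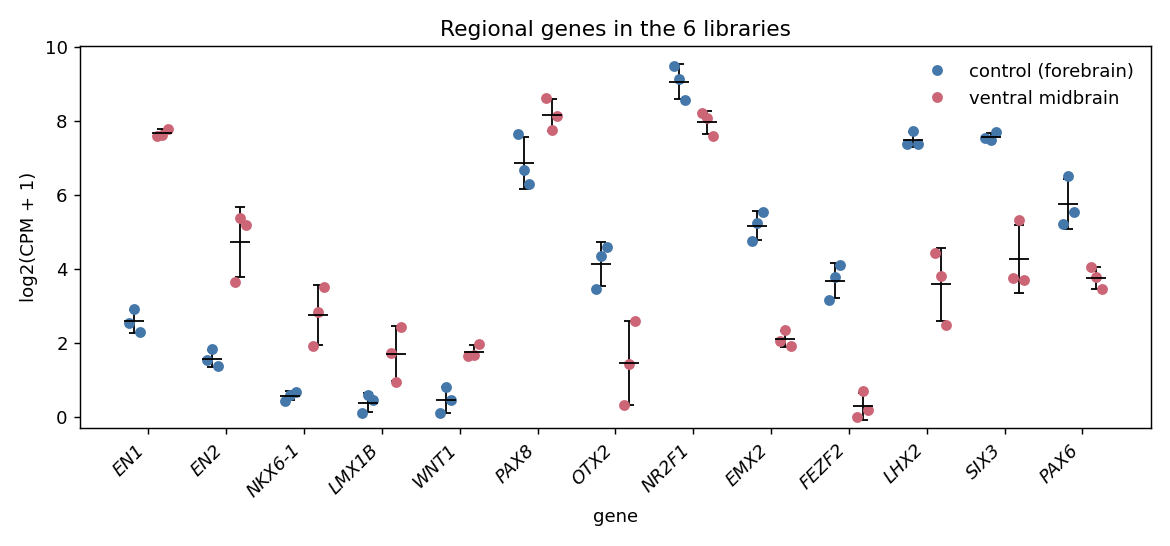
Level of 13 regional genes as log2(CPM + 1), with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3 per group). EN1 lies higher in all 3 ventral midbrain libraries (mean 202 CPM against 5.12 CPM), and EMX2 lies lower there (mean 3.35 CPM against 35.8 CPM).

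Forebrain patterning genes fell. EMX2, a cortical patterning gene (chromosome 10, 117542444 to 117549546, GRCh38), went from 35.8 ± 9.72 CPM (SD, n = 3) to 3.35 ± 0.658 CPM (SD, n = 3), a log2 fold change of -3.42 ± 0.28 (SE; edgeR adjusted p = 0.00035). FEZF2, another cortical patterning gene, fell by 5.61 on the log2 scale, and PAX6 fell by 2.16. LHX2 fell from 180 ± 26.4 to 12.8 ± 7.95 CPM and SIX3 from 189 ± 13.8 to 21.2 ± 15.5 CPM, but with the replicate block their adjusted p was 0.067 and 0.11. LMO4 fell by 0.87. In all, 7 of the 14 measured forebrain genes fell and none rose, with 8 falling in the blocked fit and 11 adjusted over the list alone. NR2F1 was at 549 and 251 CPM (edgeR adjusted p = 0.052, and 4.6e-05 with the replicate block). ZIC2 was at 83.2 and 87.6 CPM. The list stood lower than other genes (camera adjusted p = 6.0e-15), with adjusted p = 0.096 with an estimated correlation. Leaving out 1 library ended the calls of LHX2 (4 of 6 libraries), SIX3 (5 of 6), PAX6 (4 of 6) and LMO4 (4 of 6), and the fit with no low-count filter did not call LHX2 or SIX3. Neither the gene-length offset nor the deposited normalized values called PAX6 or LMO4.

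The hindbrain and spinal cord list did not pass (camera adjusted p = 0.15), with 5 of 6 measured fold changes negative. Of these members 0 passed edgeR's test, with 1 at an unadjusted p under 0.05, 1 past DESeq2's test and 0 past voom's. Adjusted over the list alone, 1 was lower and 0 higher. In the blocked fit GBX2, at 1.1 and 4.25 CPM, had an adjusted p of 0.022, and IRX3, at 348 and 162 CPM, one of 0.0029. The HOX genes of the list were too low to be tested. None of the 12 measured Hedgehog pathway genes passed edgeR's test (camera adjusted p = 0.97), with 0 at an unadjusted p under 0.05 and 0 by DESeq2 or voom. GLI1 was at 0.797 and 0.763 CPM, and PTCH1 at 11.2 and 14.0 CPM.

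Of 38 general astrocyte genes 34 were measured, and 4 of these rose while 30 did not pass. AQP4, the water channel of astrocyte endfeet, rose from 3.86 ± 2.25 to 30.5 ± 17.2 CPM (SD, n = 3; edgeR adjusted p = 0.048). MLC1, a membrane protein of astrocytes, rose by a log2 fold change of 2.26 ± 0.30 (SE; edgeR adjusted p = 0.0045). SLC1A3, a glutamate transporter, rose from 35.4 ± 11.3 to 94.4 ± 26.7 CPM (edgeR adjusted p = 0.034). NFIA, a gliogenic transcription factor, rose by 0.83 ± 0.18, although its deposited level was 1.28 times the sum used here. Reads on transcripts outside the annotation may be missing from that sum, but the cause of the gap was not tested. GFAP was at 362 ± 96.4 and 371 ± 226 CPM (edgeR adjusted p = 0.99), S100B at 7.44 and 7.41 CPM, and SOX9 at 258 and 191 CPM (edgeR adjusted p = 0.24, and 0.030 with the replicate block). VIM was at 3609 and 4485 CPM. No read was assigned to GJB6 or HEPACAM in any library, and SLC6A11 and ETNPPL had 0 to 5 reads per library, too few to be tested. The list as such did not pass (camera adjusted p = 0.55), and in the blocked fit 6 members were higher and 6 lower. Adjusted over the list alone, 5 were higher and 2 lower. Of these 4 genes, MLC1 kept its call with each library left out, and AQP4 lost it in 4, SLC1A3 in 4 and NFIA in 5 of the 6 fits. In addition, voom did not call AQP4, and neither the gene-length offset nor the deposited normalized values called NFIA. FOXJ1 and DNAH9, genes of motile cilia in the choroid plexus and ependyma list, did not pass but were higher with AQP4 in the blocked fit, at 10.2 and 62.4 CPM and at 2.76 and 7.05 CPM (edgeR adjusted p = 0.087 and 0.083, and 0.0013 and 0.028 with the replicate block). The potassium channel gene KCNJ16 rose from 1.85 to 13.9 CPM, the single change among 21 measured ion channels and transporters (camera adjusted p = 0.15).

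**Figure D2:**
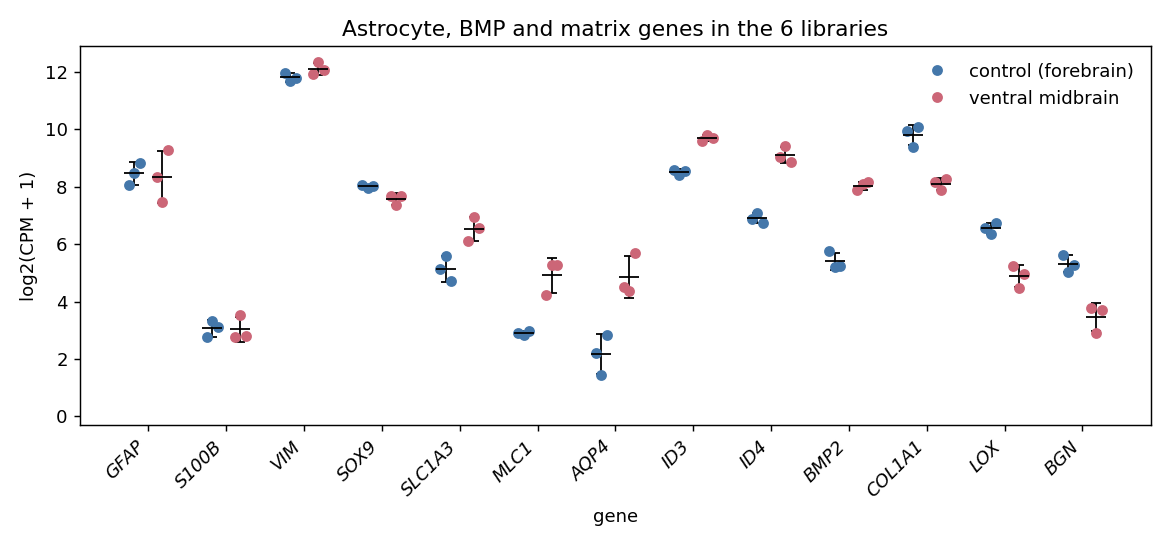
Level of 13 astrocyte, BMP and matrix genes as log2(CPM + 1), with 1 point per library, a bar at the mean and whiskers of 1 SD (n = 3 per group). GFAP overlaps between groups (362 and 371 CPM), ID4 lies higher (119 and 561 CPM) and COL1A1 lower (910 and 277 CPM) in ventral midbrain libraries.

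Signalling genes changed in both directions. Of 26 measured genes of the FGF, BMP and retinoic acid response list, 4 rose and 1 fell, with 9 and 1 in the blocked fit and 9 and 1 adjusted over the list alone. ID4, a BMP-responsive inhibitor of helix-loop-helix factors, rose from 119 ± 14.5 to 561 ± 117 CPM (SD, n = 3; log2 fold change 2.23 ± 0.19; edgeR adjusted p = 0.00035). ID3 rose by 1.19 ± 0.15, and SMAD6, a BMP feedback inhibitor, by 0.98 ± 0.22. BMP7 fell from 12.3 ± 2.49 to 2.09 ± 0.842 CPM. BMP2, outside that list and among the 5 genes with the smallest p, rose from 42.0 ± 9.46 to 262 ± 25.9 CPM (edgeR adjusted p = 0.0002). The list stood higher than other genes (camera adjusted p = 0.0046), with adjusted p = 0.47 with an estimated correlation. Of 21 measured WNT pathway genes, NKD2 rose and WIF1 and FZD5 fell (camera adjusted p = 0.76), and WIF1 had an adjusted p of 0.11 with the replicate block. Leaving out 1 library ended the calls of SMAD6 (6 of 6 libraries), FZD5 (4), WIF1 (3) and NKD2 (1), and SMAD6 was called neither with the gene-length offset nor with the deposited normalized values.

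Of 25 measured mesenchymal and fibroblast genes 4 fell, and of 32 measured matrix genes 5 fell. COL1A1, a fibrillar collagen gene, went from 910 ± 213 to 277 ± 38.4 CPM (SD, n = 3; edgeR adjusted p = 0.0037), and COL3A1, PRRX1 and FOXC1 fell by 2.0, 2.76 and 2.18 on the log2 scale. In this list 7 members were lower and 1 higher in the blocked fit, and 8 lower and 2 higher adjusted over the list alone. THY1 was at 262 and 262 CPM and POSTN at 65.8 and 124 CPM (edgeR adjusted p = 0.060, and 0.0003 with the replicate block). The crosslinking enzyme LOX fell from 93.5 ± 12.4 to 29.2 ± 7.62 CPM, and LAMA4, BGN, FBN2 and LOXL1 fell too. Of the matrix list 13 members were lower and 4 higher in the blocked fit, and 11 lower and 3 higher adjusted over the list alone. The 4 higher ones, named after their values were seen, were TIMP3, COL4A1, COL4A2 and MMP14. Both lists stood lower than other genes (camera adjusted p = 0.013 and 0.028), with adjusted p = 0.69 for each with an estimated correlation. The mesenchymal list lost its call without ventral midbrain replicate 3 (adjusted p = 0.18), and the matrix list without that library or control replicate 2 (highest adjusted p = 0.31). Leaving out 1 library ended the calls of LOXL1 (6 of 6 libraries), COL3A1 (4), FBN2 (4) and FOXC1 (1). Neither the gene-length offset nor the deposited normalized values called LOXL1, COL3A1 or FBN2, voom did not call COL3A1, and upper-quartile scaling did not call LOXL1.

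Among 4 further lists past the test, the neural progenitor and radial glia list stood higher (camera adjusted p = 0.028; adjusted p = 0.47 with an estimated correlation), and PROM1 rose from 5.23 to 19.5 CPM as 1 of 15 measured members. In this list 5 members were higher and 2 lower in the blocked fit, and 5 higher and 0 lower adjusted over the list alone. The call of the neural progenitor list was lost without control replicate 2 (adjusted p = 0.17), with the gene-length offset and with the deposited normalized values. The neurotrophic and growth factor list stood lower (camera adjusted p = 0.028; adjusted p = 0.47 with an estimated correlation), and TGFB2 fell from 1004 to 534 CPM as 1 of 22, a call that 5 of 6 left-out libraries, upper-quartile scaling, the gene-length offset and the deposited normalized values ended. The stress and unfolded protein response list stood lower with 0 of 23 members past edgeR's test, 2 at an unadjusted p under 0.05, 1 past DESeq2's test and 0 past voom's (camera adjusted p = 0.042; adjusted p = 0.75 with an estimated correlation). In the blocked fit 5 neurotrophic and 3 stress members were lower and 0 higher. The neurotrophic and stress lists lost the call without control replicate 2 or ventral midbrain replicate 3 (highest adjusted p = 0.18 and 0.82), and the stress list also with the gene-length offset, the deposited normalized values or protein-coding genes alone. The cell cycle list stood higher with 0 of 26 members past edgeR's test, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or voom (camera adjusted p = 0.042; adjusted p = 0.76 with an estimated correlation). Its mean log2 CPM was 4.81, 6.47 and 4.63 in control and 5.29, 6.86 and 4.97 in ventral midbrain replicates 2, 3 and 4, higher in ventral midbrain in each of the 3 numbered pairs. With the replicate block 8 members were higher (camera adjusted p = 1.3e-08, and 0.38 with the block and an estimated correlation). The call was lost without control replicate 2 or 4 (highest adjusted p = 0.66), and without ventral midbrain replicate 3 the direction was reversed (adjusted p = 0.52). It was also lost with DESeq2, the gene-length offset, the deposited normalized values or protein-coding genes alone.

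**Figure D3:**
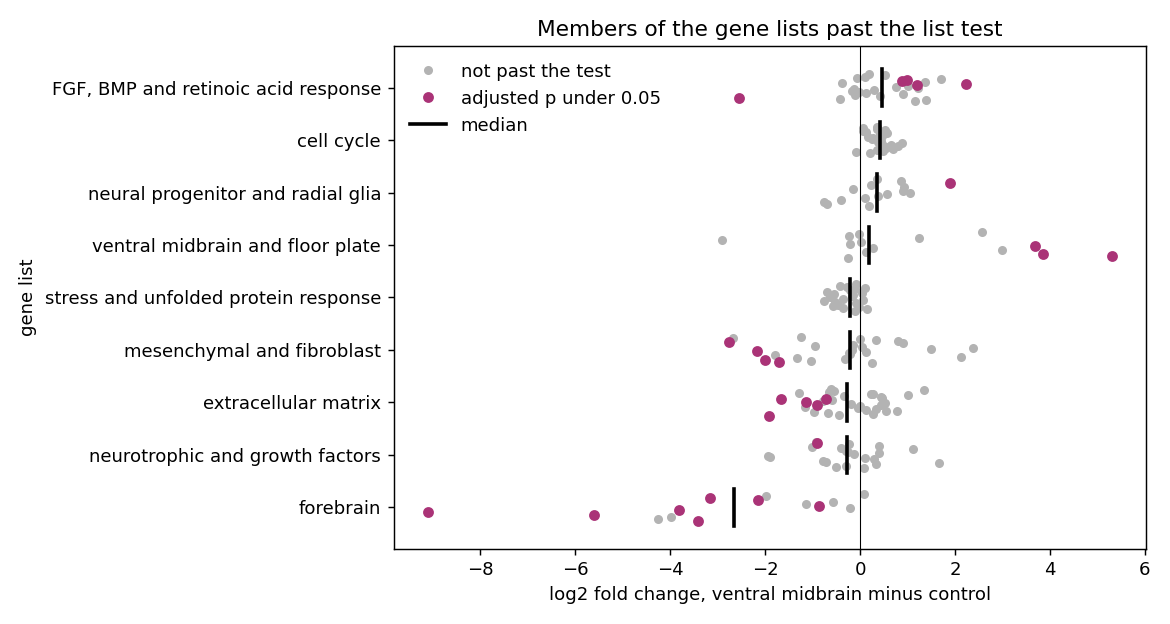
Log2 fold change of each measured member of the 9 gene lists past the list test, with 1 point per gene, filled purple where the edgeR adjusted p is under 0.05, and a black bar at the median. The forebrain median is -2.66 and that of the FGF, BMP and retinoic acid response list 0.47.

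The other gene lists did not pass. Reactive astrocyte genes, with 15 of 23 measured fold changes negative, and glycolysis and hypoxia genes, with 18 of 21 negative, came closest (camera adjusted p = 0.051 for each). S100A10 fell from 359 to 224 CPM in the first list, and PFKP rose from 64.5 to 128 CPM against the direction of the second. With the replicate block both lists stood lower (camera adjusted p = 0.0080 and 0.0054, and 0.38 and 0.44 with the block and an estimated correlation). In that fit 7 reactive astrocyte genes were lower and 3 higher, and 4 glycolysis and hypoxia genes were lower and 1 higher. Adjusted over the list alone, 5 were lower and 3 higher in the first list, and PFKP alone passed in the second. The neuron list also stood lower with the block (camera adjusted p = 0.029, and 0.54 with the block and an estimated correlation), against 0.098 without it. Of its 19 measured members CELF3 rose, from 9.68 to 55.0 CPM, while 6 were lower in the blocked fit and 4 adjusted over the list alone. These 6 were STMN2 at 1061 and 449 CPM, DCX at 58.0 and 26.4 CPM, INA at 11.1 and 2.96 CPM, NEFM at 7.61 and 1.60 CPM, NEFL at 4.95 and 1.15 CPM and NSG2 at 4.8 and 0.745 CPM. Their edgeR adjusted p was 0.095 to 0.54, and 0.0034 to 0.030 with the replicate block. MAP2 was at 234 and 252 CPM and TUBB3 at 226 and 231 CPM. KCNJ6 rose and CALB1 fell among 7 measured dopaminergic genes, BCAS1 rose and PDGFRA fell among 9 oligodendrocyte lineage genes, and GPNMB fell among 17 Parkinson disease genes (camera adjusted p = 0.98, 0.98 and 0.64). THBS2 and MEGF10 rose and SEMA5A, CHRDL1 and UNC5C fell among 27 synapse support and guidance genes (camera adjusted p = 0.10). In the blocked fit 4 of these 27 were higher and 6 lower. Leaving out 1 library ended the calls of S100A10 (6 of 6 libraries), BCAS1 (4), KCNJ6 (3), PFKP, GPNMB and UNC5C (2 each), and CELF3 and CHRDL1 (1 each). Neither the gene-length offset nor the deposited normalized values called S100A10, KCNJ6, GPNMB or UNC5C, voom called neither BCAS1 nor KCNJ6, and the offset did not call BCAS1. No member passed edgeR's test in the neural crest, choroid plexus and ependyma, endothelial and microglia, pluripotency, endoderm and skeletal muscle, cholesterol synthesis, interferon and antigen presentation, or mitochondrially encoded lists (camera adjusted p from 0.15 to 0.89). Of their 85 measured members 16 had an unadjusted p under 0.05, 5 passed DESeq2's test and 1 passed voom's. In the choroid plexus and ependyma list alone this was 5, 2 and 1 of 7 measured members (camera adjusted p = 0.64). With the replicate block FOXJ1 and DNAH9 were higher there and OTX2, KRT18 and KRT8 lower, and no read was assigned to TTR, an abundant choroid plexus transcript, in any library. In the blocked fit 4 interferon and antigen presentation genes were lower and 0 higher. The neural crest and the endoderm and skeletal muscle lists had 1 higher each, and the cholesterol list 1 lower.

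Of protein-coding genes at an average log2 CPM of at least 2, the 10 largest rises were EN1, EN2, AQP4, KCNJ16, BCAS1 and, outside the groups above, BRINP2 (log2 fold change 3.33), SOX18 (3.05), GASK1B (2.88), TSPAN2 (2.84) and ENPP5 (2.78). Among the 10 largest falls were FEZF2, LHX2, EMX2, SIX3 and, outside the groups above, LMO2 (-4.31), PRDM16 (-4.27), PLCXD3 (-3.69), DIPK1C (-3.65) and TDO2 (-3.21). Of the genes outside the groups above, TDO2 lost its call without any 1 ventral midbrain library and LMO2 without control replicate 4 (highest adjusted p = 0.094 and 0.057). POU3F2, a neural POU-domain factor, rose from 11 ± 1.29 to 57.5 ± 5.93 CPM (SD, n = 3; edgeR adjusted p = 0.00023). LINC01551, a noncoding gene, fell from 20.5 ± 2.58 to 0.150 ± 0.130 CPM (edgeR adjusted p = 0.0002).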

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

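The alternatives were planned before the data were examined, except a pseudocount of 5 for the deposited values, which was chosen after seeing the data. The 344 changed genes numbered 1012 with no low-count filter, 728 with DESeq2 and 1300 with the replicate block. They numbered 173 with the gene-length offset (165 shared), 182 with the deposited normalized values (172 shared), 216 with a pseudocount of 5 on these, and 102 at an adjusted p under 0.01. RLE scaling, upper-quartile scaling, the stricter filter, voom, protein-coding genes and the 2-fold threshold gave 283 to 355. Leaving out 1 library gave 131 (without control replicate 4) to 258 genes, with 211 without control replicate 2 and 159 and 168 without ventral midbrain replicates 2 and 4, from fewer samples. The 9 list calls became 0 with an estimated correlation (0.472 for the ventral midbrain and 0.0961 for the forebrain list), 2 with fry, 6 with the gene-length offset or the deposited normalized values at either pseudocount, 7 with protein-coding genes, 11 with DESeq2, 13 with no filter, 12 with the replicate block and 5 to 11 with a library left out (5 without control replicate 2 or ventral midbrain replicate 3). The offset and the deposited values ended the neural progenitor, stress and cell cycle calls, protein-coding genes the last 2 of these, and DESeq2 that of the cell cycle. The cell cycle list reversed without ventral midbrain replicate 3 (adjusted p = 0.523), since replicate 3 was high in both groups and leaving it out of 1 group put the mean log2 CPM at 5.13 in ventral midbrain against 5.30 in control libraries. Its adjusted p ranged from 7.7e-08 to 0.662 over the 6 fits with a library left out. Of the 60 named genes past the threshold, 31 kept the call with each library left out and 30 in every alternative run. None changed direction. The block ended the calls of LHX2, SIX3 and WIF1 and added 67 named genes; apart from these and the counts and lists given with their blocked values, it changed no other list call. The difference in mitochondrial share was -1.14 to 0.214 percentage points, and in detected genes 192 to 404, with a library left out. At this depth and n, 33% of simulated 2-fold changes were recovered, among genes with a mean CPM of at least 2 on the log2 scale.

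The gene-length tests were chosen after the result was seen. Length factors may lower the count by adding spread: the within-group SD was 1.07 times as large over all tested genes (median). A general removal of fold changes is argued against by a median ratio of fold changes of 0.999 over the 179 genes called without them alone. A median leaves open that some of these fold changes shrank. The length factor differed between groups by more than 0.5 on the log2 scale for 294 of 10644 compared genes.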

Other observations

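The tests of the BMP genes, of library scaling and of the ADORA2A locus were chosen after the results were seen, as were the genes named in this part. The noncoding gene EMX2OS went from 29.3 to 1.97 CPM (edgeR adjusted p = 0.0037) and SIX3-AS1 from 8.56 to 0.70 CPM (edgeR adjusted p = 0.015), though antisense genes are uncertain without knowing whether strand was counted. PROX1, a homeobox gene, rose from 5.85 to 32.7 CPM (edgeR adjusted p = 0.00035) and RFX4, a neural transcription factor, from 69.8 to 210 CPM (edgeR adjusted p = 0.0031). CYP1B1, a cytochrome P450, fell from 1836 to 391 CPM (edgeR adjusted p = 0.0037), EFEMP1, a matrix protein, from 213 to 57.0 CPM (edgeR adjusted p = 0.00035) and LGALS3 from 263 to 67.0 CPM (edgeR adjusted p = 0.0027).

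ID3, ID4 and SMAD6 rose, and a candidate explanation is higher BMP signalling. Of 11 measured BMP genes of the fixed list, 9 had positive fold changes (all 7 response genes, with 3 past the test). Of its ligands BMP7 fell, BMP4 was lower without passing and GDF7 was higher without passing (log2 fold change 1.21). Its antagonist NOG was also higher without passing (1.37). Outside the list, the ligand BMP2 rose (2.64) and BMP6 fell (-1.94). The 9 FGF genes had a median of -0.03, and this split of the list was made after the values were seen. Further BMP genes, 10 of them measured, did not pass limma's camera as a list (unadjusted p = 0.0715, and unadjusted p = 0.236 with an estimated correlation), but did with the replicate block (camera unadjusted p = 0.0114). That list was written without ATOH8, SMAD9, MSX1 and MSX2 although the values of these 4 had been seen; with these 4 added it passed (camera p = 0.0125, p = 0.00208 with the replicate block, and p = 0.117 with an estimated correlation), with ATOH8 and SMAD9 rising and MSX2, a BMP target, falling by 2.84 on the log2 scale. The hypothesis stays open. Library scaling moves all genes of a library alike, so these 3 genes were set against the median tested gene of the same library. In unscaled reads ID3, ID4 and SMAD6 were then higher by 1.16 ± 0.08, 2.19 ± 0.18 and 0.958 ± 0.19 (SE) on the log2 scale. The median log2 fold change of all tested genes was 0.0143 in the main fit, so this had to come near the fold changes already called. It shows a rise against the median gene and cannot decide further on scaling.

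ADORA2A rose and SPECC1L-ADORA2A fell, both on chromosome 22 on the same strand, with gene ends at 24442360 and 24442356 (GRCh38). ADORA2A had 0 reads in each control library and SPECC1L-ADORA2A 0 in each ventral midbrain library. Their summed reads differed by -0.68 ± 0.60 on the log2 scale, which is consistent with reads shared between overlapping gene models. A change of the total from the locus stays open (adjusted p = 0.754), as the SE is wide.

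The 344 genes compare with at most 1 gene in the other splits of the 6 libraries into 3 and 3, and the 9 lists with at most 8. The real split alone gave as many in each case (1 of 10 splits), and 10 splits are too few for a share under 0.05. Each other split mixes libraries of both groups, so a group difference adds to its spread and lowers its gene count. The other splits therefore do not show how many genes would pass with no group difference. They gave 1 to 8 lists, so camera at the preset correlation also called lists where the groups were mixed. The 3 other splits that part all 3 numbered pairs gave at most 1 gene and 4 lists, and the 6 that part fewer gave at most 1 gene and 8 lists.

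Of 936 tested transcripts outside the annotation, 1 passed edgeR's test (lower in ventral midbrain) and 45 had an unadjusted p under 0.05. No chromosome stood apart from the others (0 of 23 by limma's camera, smallest adjusted p = 0.979, and 0.957 with an estimated correlation, with 0 at an unadjusted p under 0.05 at either correlation setting).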
